A study of Mus musculus with 10 samples.

How the data were processed

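The deposited files hold UMI counts per barcode for 31053 features and, separately, counts of sample tags per barcode. Per the submitters' processing notes the reads were aligned to mm10 with Cell Ranger 6.0.0; per the file headers the matrices of experiments 1 and 3 came from version 6.0.0 and those of experiment 2 from version 7.0.0, so levels in experiment 2 were not compared with the other experiments. The authors gave no normalised values. CPM, log2 ratios and percentages in the text were computed from the deposited counts.

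Barcodes with at least 1000 UMI, at least 500 genes and under 10% mitochondrial UMI were kept, which left 22020, 18653, 28991, 14479 and 18607 cells of the untreated spleen, TLI-ATS spleen, untreated LN, EpoR-positive and EpoR-negative libraries. In experiments 1 and 3 the tag barcodes matched the RNA barcodes after bases 8 and 9 were complemented (21805, 18485 and 26297 matches, against 23, 14 and 35 as written). Tag counts were divided by each tag's median, and a cell with at least 10 tag counts was assigned where its top tag held at least 80% of the scaled counts. The tag key of experiment 2 puts 2 of its tags in the other library than the titles do, so these were assigned by elimination from the library titles; the titles call the LN untreated while the protocol text names TLI-ATS for both organs. Over all cells with a given top tag, before that rule, the other tag had a median share of 4.58% and 2.69% in untreated spleen (EpoR-intact and EpoR-deleted), 3.38% and 2.98% after TLI-ATS and 12.4% and 9.33% in LN of experiment 3. In experiment 2 it was 5.55% and 1.93% in spleen (EpoR-positive and EpoR-negative) and 27.4% and 21.5% in LN, where 536 of 2038 and 1115 of 2452 cells met the rule. Assignment by mixtures kept 1708 and 1924 cells of those LN pools, against 494 and 1017. Scrublet called 6.32%, 5.69%, 8.53%, 2.60% and 4.54% of cells doublets in the same library order. Among cells of mixed tags the called share was 25.4%, 25.0%, 18.6%, 17.2% and 34.4%, and among cells of clean tags 3.16%, 2.72%, 5.16%, 1.05% and 2.27%.

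Each experiment was clustered alone with scanpy 1.11.5 (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1). Clusters were left out where the mean log2 fold of another cell type's markers exceeded 1.5 and at least 3 of these markers were detected. Clusters led by macrophage or monocyte genes or by pancreatic enzymes, and those of low depth or with few own markers, were left out too. In all, 19, 165, 471, 1283 and 597 cells were left out in the same library order. A cluster was mature where the mean log2 level of mature dendritic cell genes exceeded that of immature cDC1 genes by over 2.5, a threshold set after the data were seen. A cluster with more leading markers of another list than of its own carried no name and was not counted as mature, but stayed in the comparisons over all cells; it was in neither the mature nor the non-mature set of the tests. In experiment 1 clusters 10 and 18 were mature, in experiment 2 clusters 7 and 11, and in experiment 3 clusters 0, 1, 3, 4, 5, 8, 9 and 10.

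For single contrasts UMI were summed per pool and log2 ratios taken of CPM with a pseudocount of 1 CPM. CPM have exact Poisson 95% intervals. Intervals of log2 ratios are exact conditional binomial intervals of the counts without the pseudocount, so at low levels they lie outside the printed ratio. Shares have exact Clopper-Pearson 95% intervals, which were combined by the square-and-add method for differences. Medians of fixed gene lists cover members with at least 30 CPM in the higher pool, with intervals from 2000 Poisson draws, and percentiles are among 10000 random lists of the same size matched on expression in 20 bins. Groups, tests, lists and the rule for named genes were set before the data were examined. The rule takes Epor in every pool, then per single contrast the 12 genes with the largest ratio in each direction among genes of at least 30 CPM whose interval excludes 1.5-fold. Per tested contrast it takes the 12 largest log2 fold changes in each direction among genes at an adjusted p under 0.05. Of each fixed list described it takes 2 to 4 members with the largest ratio among those of at least 10 CPM. Mitochondrial, ribosomal protein, sex-linked and unnamed gene models were left out of it. Ccr7, Fscn1, Il4i1 and Ccl5 as markers of clusters, and Igkc and Hbb-bs as markers of other cells, were given apart from it. No list test with an estimated correlation was run.

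Tested contrasts used edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM factors, glmQLFit and glmQLFTest, two-sided) with the context or organ as a block, and Benjamini-Hochberg adjustment over the genes tested. The genotype tests had 6 pools and 2 residual degrees of freedom, and the test of the sort 4 pools and 1. DESeq2 1.42.0 was the alternative. A paired test by animal was not possible because the tags mark pools, not animals. Alternatives for single contrasts were TMM factors, a pseudocount of 5 CPM, a minimum of 10 CPM, a filter of 2000 UMI and 5% mitochondrial UMI, a top tag share of 95%, and doublets kept. Shares were also computed with Leiden resolution 0.5 and with every cell thinned to 2000 UMI.

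The steps were tested on simulated data drawn from the pools' means, with 200 changed genes, and for the edgeR steps with fitted dispersions. The edgeR steps recovered 80.6%, 98.5% and 100% of genes changed 1.5-fold, 2-fold and 4-fold over all cells (2 of 188 calls false), 74.6%, 95.5% and 100% within mature cells (6 of 186 false), 82.1%, 98.5% and 100% outside them (13 of 200 false) and 82.1%, 91.0% and 100% for the sort (18 of 200 false). With gene-wise dispersions the false calls were 20 of 195, 10 of 195, 52 of 241 and 4 of 183 in the same order. Recovery at 1.5-fold was then 68.7%, 80.6%, 86.6% and 74.6%. The changed genes were not drawn from the lowest expressed genes, so recovery there was not tested. For the single contrasts the counts were Poisson draws from a mean shared by both pools, without variation between animals or libraries. There the intervals held the simulated ratio for 93.5% to 97.5% of genes, and 0 unchanged genes passed 1.5-fold. This checks the computation under counting error only and cannot show how often pools of other animals would differ.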

Results

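Type 1 conventional dendritic cells (cDC1s), which take up dead cells and cross-present their antigens to CD8 T cells, were profiled from mouse spleen and lymph node (LN) by droplet single-cell RNA sequencing with counts of unique molecular identifiers (UMI) at transcript 3′ ends. The series asks what the erythropoietin receptor (EpoR, gene Epor) does in these cells, at rest and after TLI-ATS, a conditioning by total lymphoid irradiation with antithymocyte serum that favours transplant tolerance. There were 5 RNA libraries in 3 experiments, each with a library of sample tags, and the tags divided the cells into 10 pools. In experiment 1, spleen cDC1s of mice with floxed Epor and no Cre (EpoR-intact) and of mice in which Xcr1-Cre removes the floxed gene (EpoR-deleted) shared a library, untreated in the first library and after TLI-ATS in the second. Experiment 3 held untreated LN cells under the same 2 tags. In experiment 2, cDC1s of EpoR reporter mice were sorted into an EpoR-positive and an EpoR-negative library, each holding a TLI-ATS spleen pool and an untreated LN pool. Every group was 1 pool, so there were no replicates within a group, and intervals cover counting error only. Single contrasts of 1 pool against 1 pool therefore have values and no p.

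The untreated spleen library held 23001 barcodes and 315657821 UMI, and the TLI-ATS spleen library 19754 barcodes and 281677472 UMI. The untreated LN library of experiment 3 held 31851 barcodes and 196083419 UMI. The EpoR-positive library held 15198 barcodes and 303661895 UMI, and the EpoR-negative library 18947 barcodes and 252833388 UMI. After filtering, the untreated spleen pools kept 9293 EpoR-intact cells (123770370 UMI) and 8749 EpoR-deleted cells (110812816 UMI). The TLI-ATS spleen pools kept 7588 EpoR-intact cells (104551533 UMI) and 7577 EpoR-deleted cells (101932399 UMI), and the LN pools 7286 (43128742 UMI) and 9057 (58028219 UMI). In experiment 2 the spleen pools kept 10626 EpoR-positive cells (235940676 UMI) and 14791 EpoR-negative cells (205902367 UMI), and the LN pools 494 cells (6202849 UMI) and 1017 cells (8223324 UMI). Median depth was 21156 UMI per EpoR-positive spleen cell against 12489 per EpoR-negative spleen cell, and 11804 against 7758 in LN.

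Epor itself (ENSMUSG00000006235, mm10 chromosome 9, 21958897 to 21963576) was nearly undetected. It had 0 UMI in both untreated spleen pools, 1 UMI in the EpoR-intact and 0 in the EpoR-deleted TLI-ATS spleen pool, and 2 and 3 UMI in the EpoR-intact and EpoR-deleted LN pools. The EpoR-positive and EpoR-negative spleen pools had 2 and 0 UMI, and the LN pools of the same sort 0 and 1. A count of 0 in the EpoR-deleted untreated spleen pool allows up to 0.0333 CPM (UMI scaled to the pool's total, upper end of the 95% interval), and in the EpoR-positive LN pool up to 0.595 CPM. At this depth the Epor transcript neither separates the genotypes nor checks the sort.

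The larger mature cluster of experiment 1 had Ccr7 (the receptor that guides dendritic cells to LN), Fscn1 (an actin bundler of migrating dendritic cells), Ccl5 and Il4i1 among its leading genes. Ccr7 was not a leading gene of the mature LN clusters of experiment 3. The share of cells in mature clusters asks whether EpoR status goes with cDC1 maturation. In untreated spleen it was 5.43% of EpoR-intact cells (95% interval, 4.98% to 5.92%) and 5.20% of EpoR-deleted cells (4.75% to 5.69%). After TLI-ATS it was 10.1% of EpoR-intact cells (9.46% to 10.8%) and 3.99% of EpoR-deleted cells (3.56% to 4.45%). The EpoR-deleted pool thus differed from the EpoR-intact pool by -6.15 percentage points after TLI-ATS (-6.97 to -5.33) and by -0.234 points untreated (-0.896 to 0.430). The untreated difference has no settled direction: it was 1.06 points (0.402 to 1.71) among cells with 95% of a single tag and -1.73 points (-2.48 to -0.980) at Leiden resolution 0.5, against -5.65 and -7.36 points after TLI-ATS. In untreated LN, where most cDC1s were mature, the shares were 90.1% (89.4% to 90.8%) and 86.4% (85.7% to 87.1%), a difference of -3.71 points (-4.70 to -2.71). Clusters 9 and 10 of LN counted as mature by list level, with 0 mature dendritic cell list genes among their 10 leading genes. Cluster 10 held 27.7% of EpoR-intact and 12.5% of EpoR-deleted LN cells. Between EpoR-positive and EpoR-negative spleen cells the shares of 1.79% and 1.74% differed by 0.0438 points (-0.287 to 0.383), or by 0.859 points (0.360 to 1.41) with 95% of a single tag, and between the LN pools of that sort the shares of 98.0% and 99.2% differed by -1.24 points (-2.96 to 0.0565). Cells had been sorted on XCR1, whose transcript is low in mature cells, so shares are of sorted cells. Clusters whose leading genes held more markers of another list than of their own carried no name and were not counted as mature; led by S100a10, Ccr2 and S100a6 in spleen, they held 2.67% and 4.21% of the EpoR-intact and EpoR-deleted untreated spleen cells, 3.53% and 7.19% after TLI-ATS, and 7.07% and 7.42% in LN. Mature cells of the TLI-ATS spleen had a median of 8480 UMI in the EpoR-intact and 5970 in the EpoR-deleted pool.

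**Figure D1:**
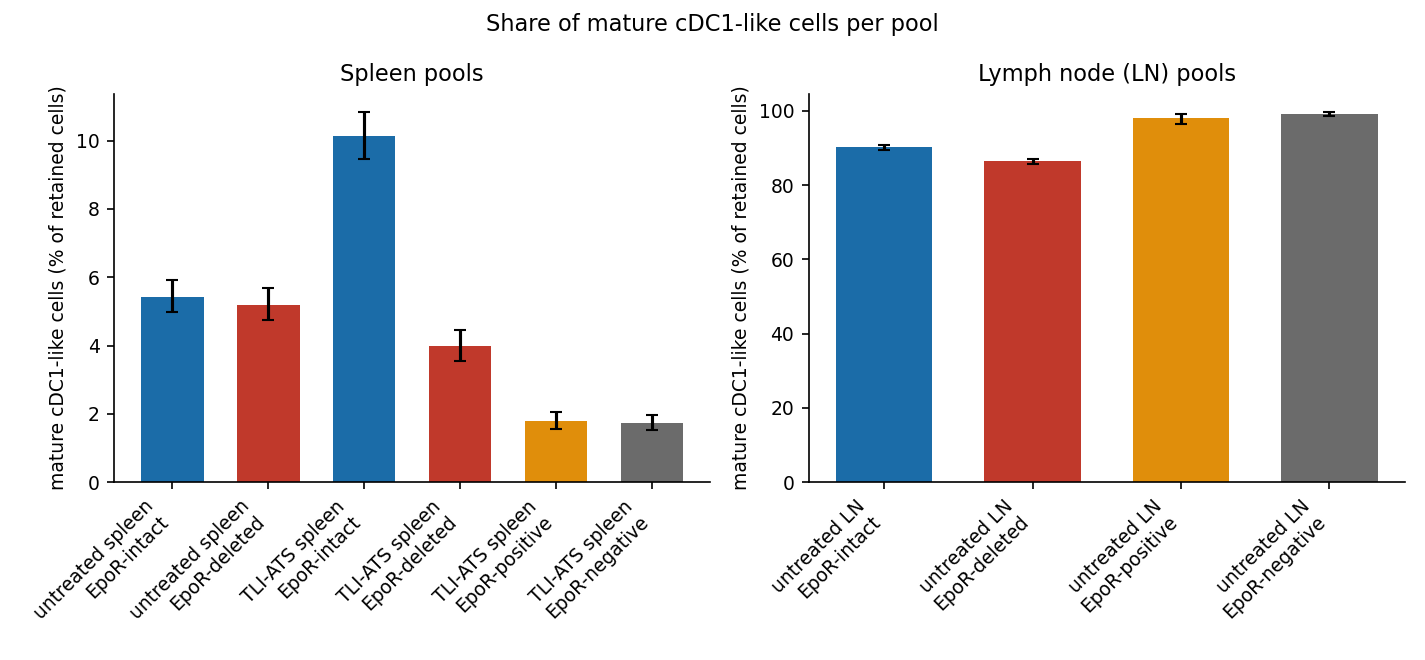
Share of cells in mature clusters (percent of retained cells, vertical axis) in each of the 10 pools, with bars for 95% counting intervals. The EpoR-intact TLI-ATS spleen pool stands at 10.1% and its EpoR-deleted partner at 3.99%.

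The first pair of contrasts asks how TLI-ATS changes the spleen cDC1 transcriptome with and without EpoR. In EpoR-intact cells after TLI-ATS, interferon-inducible genes stood higher: the GTPases Iigp1 (35.6 against 4.09 CPM) and Irgm1 (log2 ratio 1.29), and Zbp1, a sensor of Z-form nucleic acid (35.5 against 12.8 CPM). Members counted as measured here and below are those with at least 30 CPM in the higher pool, so they differ between contrasts. All 8 measured members of the type I interferon list were higher, with a median log2 ratio of 0.61 (percentile 100 among 10000 random lists of like expression). Itgae, the integrin chain CD103 of cDC1s, was at 101 against 27.3 CPM (1.85, interval 1.83 to 1.94), and the galectin gene Lgals1 at 120 against 50.1 CPM. Genes of mature dendritic cells stood higher in 13 of 14 members, with a median of 0.36 (0.34 to 0.39), among them Fscn1 at 92.0 against 44.1 CPM. Regulatory and co-inhibitory genes had a median of 0.29, with Entpd1, which degrades extracellular ATP, at 0.88. Other genes with large ratios were Glipr2 (1.62), Gnb4 (1.30), Zyx (1.14), Sept3 (1.13), Ly6a (1.10) and Cd63 (80.6 against 39.8 CPM).

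Lower after TLI-ATS in the EpoR-intact pool were genes of acute stimulation: Egr1 at 95.3 against 377 CPM (-1.97, interval -2.02 to -1.95), Egr3 (-1.05), Junb (-1.07), and the nuclear receptors Nr4a1 (-1.12), Nr4a2 (-1.32) and Nr4a3 (-1.09). Il1b, which encodes an inflammatory cytokine, was at 188 against 553 CPM, and Apol7c, an apolipoprotein L family gene of cDC1s, at 150 against 516 CPM. P3h2 (-1.47), Galc (-1.15), Hepacam2 (-1.12) and Gcnt2 (-1.05) also stood lower. The list of immediate early and dissociation genes had a median of -0.56 (percentile 0). Among p53 targets, whose median was 0.31, the cell cycle inhibitor gene Cdkn1a stood at 58.8 against 31.8 CPM. The pools lay in different clusters: a cluster led by Itgae, Entpd1 and Pfkp held 26.9% of EpoR-intact cells after TLI-ATS and 0.990% untreated, and a cluster led by Egr3, Nr4a2 and Egr1 2.61% and 35.8%. With each cluster given the same weight in both pools, the log2 ratio of Itgae went from 1.85 to 1.72, that of Egr1 from -1.97 to -1.03, that of Egr3 from -1.05 to -0.24, that of Il1b from -1.56 to -0.78 and that of Iigp1 from 2.85 to 1.54.

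In EpoR-deleted cells the pattern after TLI-ATS was shared in part. Itgae (49.4 against 13.6 CPM), Lgals1 (208 against 87.3 CPM), Zbp1 (1.15), Sept3 (1.23) and Ly6a (1.03) stood higher after TLI-ATS here too, and the interferon list had a median of 0.32. The mature dendritic cell list instead stood lower in all 10 measured members, with a median of -0.40 (-0.44 to -0.37; percentile 0), including the chemokine gene Ccl22 (-0.86) and Ccr7 (-0.84). Inflammatory cytokines and chemokines were lower in all 9 measured members (median -0.77), led by Ccl3 (-2.30), Il1b (102 against 462 CPM) and Ccl4 (192 against 753 CPM). NF-kB pathway genes had a median of -0.58, with its inhibitors Tnfaip3 at -1.03 and Nfkbia at 166 against 334 CPM. The division genes of the G2/M list stood higher in all 12 members (median 0.59, percentile 100), among them the cyclin genes Ccnb2 (0.84) and Ccnb1 (0.78), alongside histone genes such as Hist1h2br (1.23), Hist1h2bb (1.09), Hist1h2ap (1.04), Hist1h1d (0.96), Hist1h2ab (0.95) and Hist1h3f (0.92). Lower were Phlda1 (-2.73), Apol7c (-2.48), Gcnt2 (-2.38), Nr4a3 (-2.09), Egr1 (48.2 against 195 CPM) and the heat-shock genes Hspb1 (6.00 against 80.3 CPM), Dnajb1 (-2.20), Hspa1a (415 against 1617 CPM) and Bag3 (-1.89). Igkc, an immunoglobulin light chain gene of B and plasma cells, was at 90.9 against 3.43 CPM (4.38). The cluster led by Itgae held 9.48% of EpoR-deleted cells after TLI-ATS and 0.183% untreated, and a cluster led by Dnajb1, Hspa1a and Phlda1 0.779% and 28.5%. With equal cluster weights the log2 ratio of Itgae went from 1.79 to 1.69, that of Egr1 from -1.997 to -1.036, that of Il1b from -2.17 to -1.27 and that of Hspb1 from -3.54 to -3.17. In both contrasts treatment coincides with the library, so the 2 cannot be told apart.

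**Figure D2:**
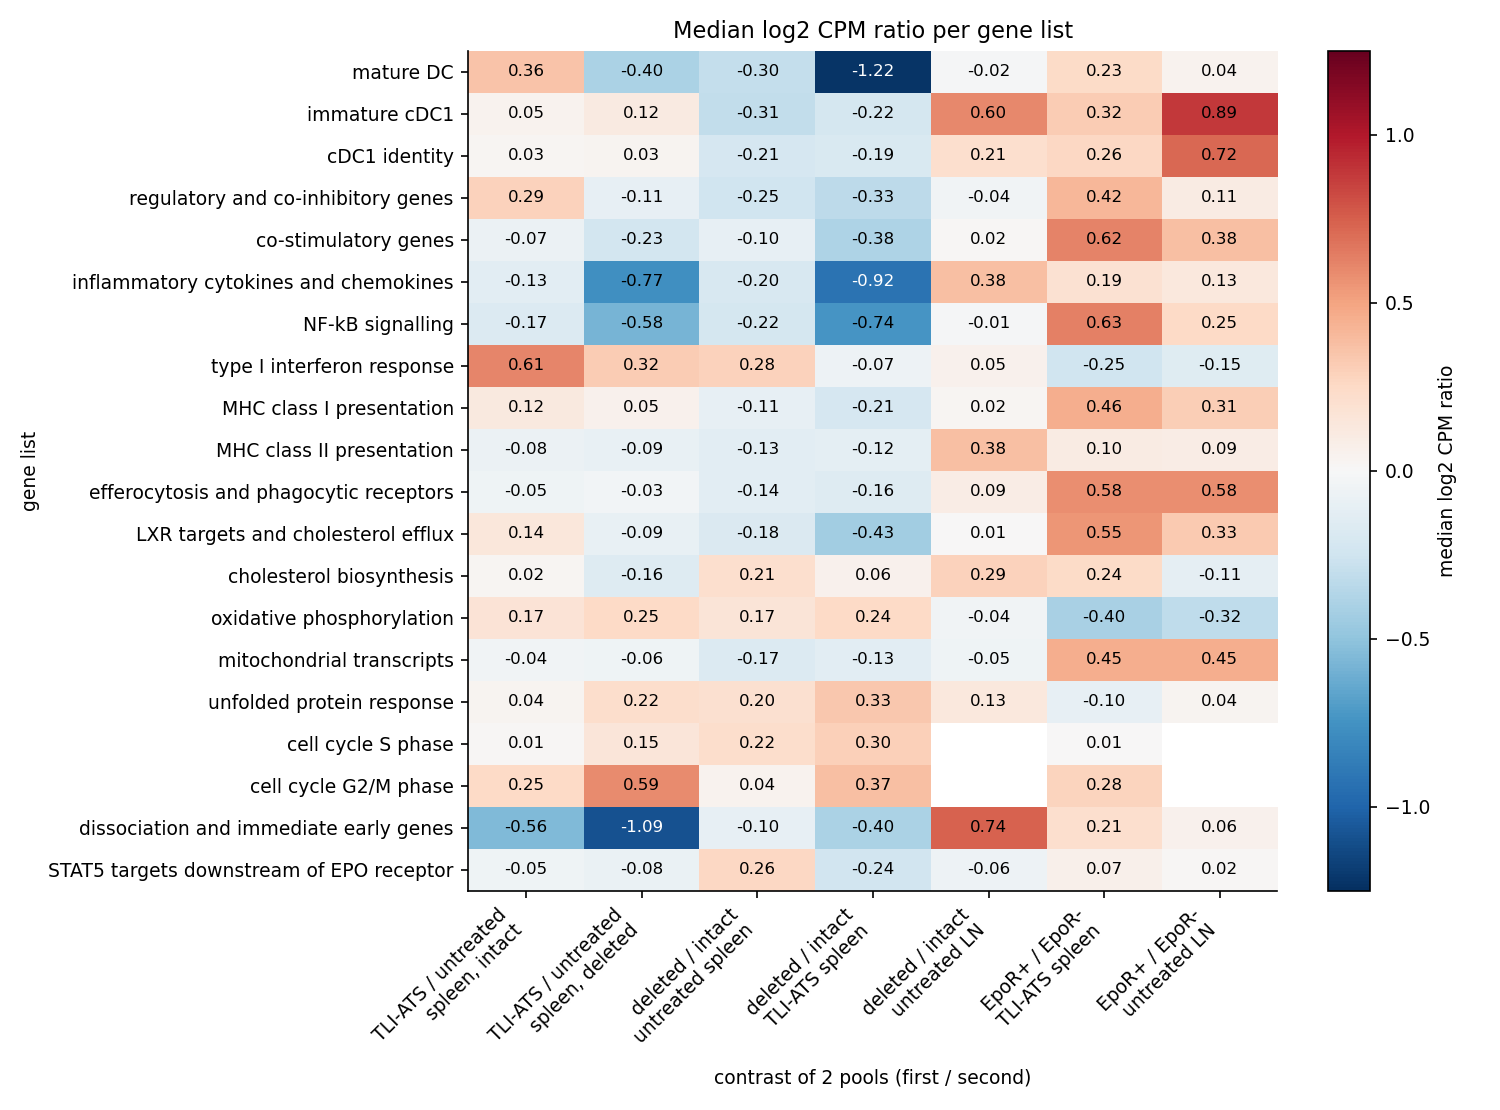
Median log2 CPM ratio of the members of fixed gene lists (rows) with at least 30 CPM in the higher pool, in the 7 single contrasts (columns), by colour, without correction for the median shift of all genes. The mature dendritic cell list stands at 0.36 and -0.40 after TLI-ATS in EpoR-intact and EpoR-deleted spleen cells, and at -1.22 between the TLI-ATS genotypes.

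The contrasts of genotype ask how the EpoR-deleted pool differs from the EpoR-intact pool within a context. In TLI-ATS spleen, all 14 measured genes of the mature dendritic cell list were over 1.5-fold lower in the EpoR-deleted pool, with a median log2 ratio of -1.22 (-1.26 to -1.18; percentile 0). Ccr7 stood at 40.2 against 164 CPM (interval of the log2 ratio -2.08 to -1.98), Fscn1 at 30.6 against 92.0 CPM and Il4i1, an enzyme that restrains T cells, at 14.1 against 47.3 CPM. Il12b, the p40 chain of interleukin-12, was at 35.7 against 217 CPM (-2.57, interval -2.66 to -2.56). Cd274, which encodes the checkpoint ligand PD-L1, was at 10.7 against 38.7 CPM, and the T cell attractant gene Ccl5 at 131 against 408 CPM. Inflammatory genes had a median of -0.92 (9 of 10 members lower), NF-kB genes -0.74 (12 of 12 lower, Relb at -1.18), regulatory genes -0.33 (8 of 9 lower) and co-stimulatory genes -0.38, with Cd80 at -1.19 and Cd83 at -0.99. Also lower were Nr4a3 (17.1 against 83.6 CPM), Egr3 (-1.78), Gclc (-1.82), Cd63 (-1.80), Rasgef1b (-1.67), Gadd45b (-1.65) and Glipr2 (-1.60). These values are over cells of all clusters, and the deleted to intact ratio of mature shares in this pair was 0.393. Within mature cells the log2 ratio of Il12b between these pools was -0.84. Equal cluster weights were not applied over all cells here, so cell shares and levels per cell are not separated.

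Higher in the EpoR-deleted TLI-ATS pool were genes of protein folding and division. The unfolded protein response list was higher in all 14 members (median 0.33, percentile 99.99), with Creld2 at 0.57 and the disulfide isomerase gene Pdia6 at 0.54. S phase genes were higher in 12 of 12 members (median 0.30) and G2/M genes in 12 of 12 (median 0.37), and oxidative phosphorylation genes in 24 of 24 (median 0.24). The monocyte list had a median of 0.69 over 4 members, of which the chemokine receptor gene Ccr2 was at 72.9 against 33.7 CPM (1.09, interval 1.05 to 1.17), Ms4a6c at 0.74 and Plac8 at 0.63, while Lyz2 was at -0.20. S100a10 (0.88), Mndal (0.87), Ifi203 (0.82), Gpr183 (0.80), Lgals1 (0.79), Ifi27l2a (0.75), Kctd14 (0.70), Srm (0.67) and S100a6 (0.65) also stood higher. Igkc was at 90.9 against 20.1 CPM.

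In untreated spleen the EpoR-deleted pool carried more heat-shock transcripts. The chaperone genes Hspb1 (80.3 against 9.80 CPM), Hspa1b (1425 against 352 CPM; 2.01, interval 2.00 to 2.03), Hspa1a (1617 against 433 CPM), Dnajb1 (1.79), Hsph1 (1.52) and Hsp90aa1 (1.15) and the co-chaperone gene Bag3 (1.78) led the higher genes, with Phlda1 (1.94), Ifi203 (1.31), Rhob (1.14), Ccl3 (1.14) and S100a10 (1.07). Lower were Egr3 (51.9 against 209 CPM; -1.99, interval -2.05 to -1.97), Nr4a2 (-1.43), Nr4a3 (-1.22), Il12b (61.5 against 148 CPM), Tnfaip2 (-1.26), Apoe, which encodes a lipid carrier (-1.23), the co-stimulatory ligand gene Cd80 (-1.08), Ier3 (-1.09), Slc16a6 (-1.09), Fndc5 (-1.05), Pde4b (-1.03) and Trib1 (-1.03). The mature dendritic cell list was lower in 12 of 12 members (median -0.30), and the immature cDC1 list in 11 of 13 (median -0.31), with Xcr1 at 265 against 489 CPM. The untreated genotypes lay in different clusters: a cluster led by Dnajb1, Hspa1a and Phlda1 held 28.5% of EpoR-deleted and 6.91% of EpoR-intact cells, and a cluster led by Egr3, Nr4a2 and Egr1 4.30% and 35.8%. With each cluster given the same weight in both pools, the log2 ratio of Hspa1b went from 2.01 to 1.48, that of Hspb1 from 2.91 to 2.22, that of Egr3 from -1.99 to -0.65 and that of Nr4a3 from -1.22 to -0.17. S phase genes were higher in 10 of 10 members (median 0.22), oxidative phosphorylation genes in 24 of 24 (median 0.17) and the monocyte list had a median of 0.38.

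In untreated LN the 12 genes with the largest ratios were all higher in the EpoR-deleted pool, and no gene met the rule for naming on the lower side. They were heat-shock genes, Hspa1b (1059 against 389 CPM; interval of the log2 ratio 1.42 to 1.47), Hspa1a (1.35), Dnajb1 (1.06) and Hsph1 (1.01), genes of acute stimulation, Egr1 (1.31), Atf3 (0.86) and Nr4a1 (0.84), and the inflammatory genes Ccl4 (1.38), Il1b (1.24) and Cxcl9 (145 against 67.8 CPM), with Klf2 (0.96) and Naaa (0.90). MHC class II presentation genes were higher in 8 of 8 members (median 0.38), with H2-Ab1 at 1134 against 729 CPM, cholesterol biosynthesis genes in 10 of 10 (median 0.29), with Hmgcs1 at 0.53, and immature cDC1 genes in 5 of 5 (median 0.60). The mature dendritic cell list stood at -0.02 (percentile 18.4). The tag key names the genotypes for spleen only, so the LN genotypes rest on the same tag numbers. In all 3 contexts the EpoR-deleted pools also carry the Cre and the EpoR-intact pools do not.

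**Figure D3:**
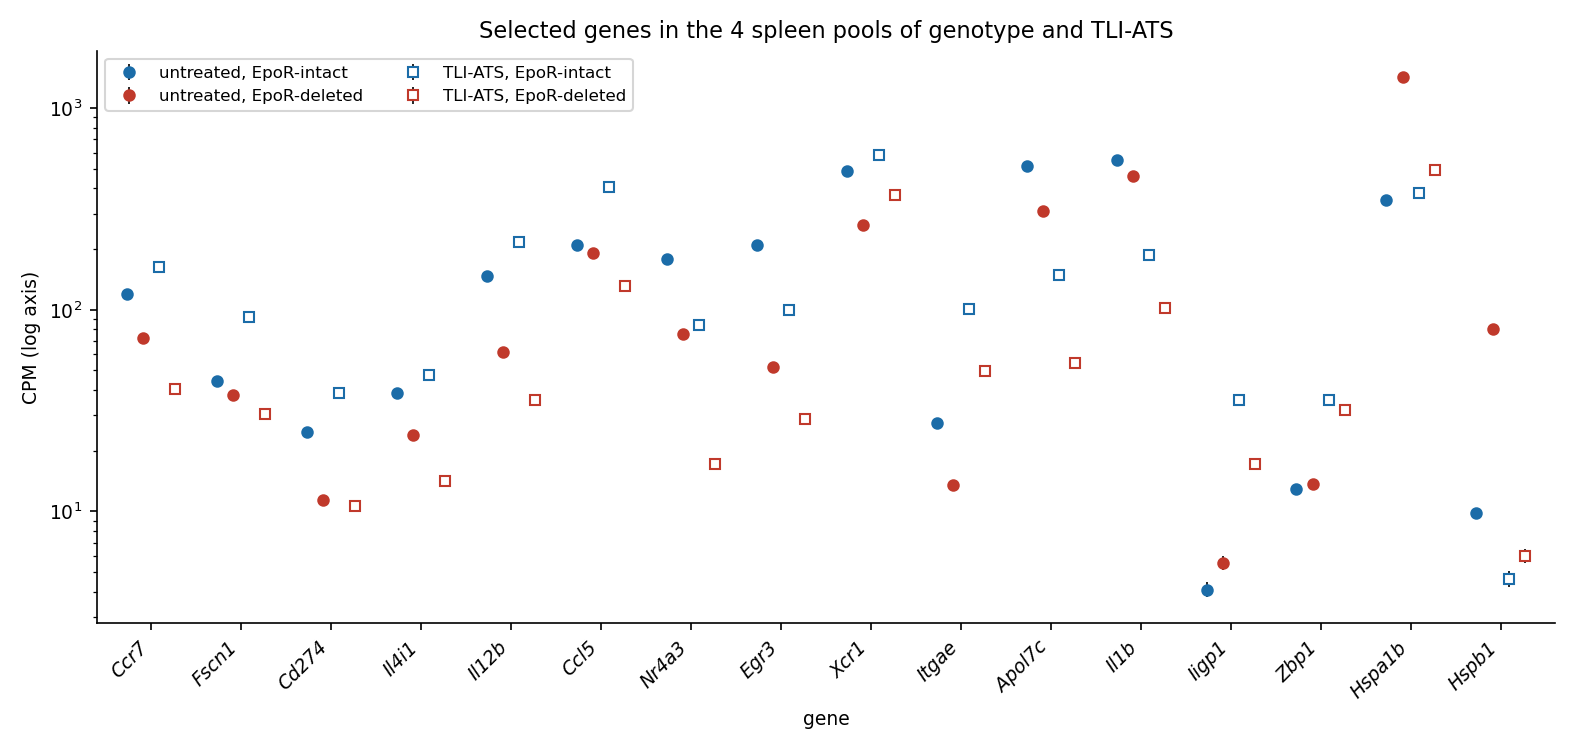
CPM (log axis) of named genes in the 4 spleen pools of experiment 1, with bars for 95% counting intervals. After TLI-ATS Il12b stands at 217 CPM in the EpoR-intact pool and at 35.7 CPM in the EpoR-deleted pool, and Hspa1b in untreated spleen at 352 and 1425 CPM.

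A genotype difference shared by untreated spleen, TLI-ATS spleen and LN was tested with edgeR, each context being a block of 1 pool per genotype. The test asks whether the average difference departs from 0, with its variation between contexts as error. It does not test whether the contexts are alike, and variation between animals within a context is not measured. Over all cells, 0 of 13542 genes passed an adjusted p of 0.05; 1433 had an unadjusted p under 0.05, and DESeq2 called 39 genes (30 higher, 9 lower in EpoR-deleted pools). All 20 tested members of the mature dendritic cell list were lower, with a median log2 fold change of -0.54, and 0 passed, adjusted over all genes or adjusted over the list alone. Of 16 STAT5 targets, genes that the EPO receptor can induce, 0 passed over all genes and 3 when adjusted over the list alone (2 higher, 1 lower). Adjusted over the list alone, 3 of 9 monocyte genes and 4 of 15 unfolded protein response genes were higher and 4 of 7 erythroid genes lower, all with 0 over all genes. Without the LN pair 990 genes passed, and without the TLI-ATS pair 2.

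Within mature cells 37 of 9295 genes changed in edgeR (34 higher, 3 lower in EpoR-deleted pools; 534 at unadjusted p under 0.05; 18 by DESeq2, all shared). Irf8 (ENSMUSG00000041515, mm10 chromosome 8, 120736358 to 120756694), the transcription factor that sets the cDC1 lineage, fell in EpoR-deleted mature cells, by a log2 fold change of -0.58 (SE 0.0965, adjusted p 0.00388). Its level was 278 against 524 CPM in untreated spleen, 439 against 682 CPM after TLI-ATS and 426 against 512 CPM in LN. Il12b (ENSMUSG00000004296) fell by a log2 fold change of -0.55 (SE 0.0994, adjusted p 0.00697), with 1201 against 1979 CPM, 1212 against 2169 CPM and 542 against 599 CPM in the same order, and Myb changed by -0.46 (adjusted p 0.0468). These 3 lower calls depend on the spleen pairs: none of them passed without the TLI-ATS pair, where 38 genes were higher and 0 lower (Irf8 -0.54, Il12b -0.39, Myb -0.41), or without the untreated spleen pair (-0.45, -0.49 and -0.39). At a 95% tag share Irf8 alone of the 3 passed, DESeq2 called Irf8 and Il12b, and with doublets kept 2 of the 3 passed. Heat-shock genes rose, with Hspa1b at 1.30 (SE 0.117, adjusted p 1.24e-06), Hspa1l at 1.35, Hspb1 at 1.16, Hspa1a at 1.05, Hsph1 at 0.96, Dnajb1 at 0.95 and Dnajb4 at 0.84. Egr1 (1.30), the granzyme inhibitor gene Serpinb9b (1.17), Pcbp4 (0.97), Wfdc17 (0.95) and Phlda1 (0.86) rose too.

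Of the inflammatory list, besides Il12b, Tnf rose (0.82, adjusted p 4.82e-05), and of the interferon list Rsad2 (0.81), an antiviral enzyme, and Oasl1 (0.50); these 3 were named after their values were seen. Adjusted over the list alone, 8 of 19 interferon genes were higher, 5 of 16 inflammatory genes higher and 1 lower, and of 20 immediate early and dissociation genes 7 higher and 1 lower (6 higher over all genes). The mature dendritic cell list had 0 of 20 changed members and the regulatory list 0 of 18, over all genes and adjusted over the list alone; among 13 STAT5 targets 0 passed over all genes, and 2 were higher and 1 lower adjusted over the list alone. The mature cells of spleen fell in 2 clusters and those of LN in 8, and the genotypes were spread over them unequally. A spleen cluster led by Ccl5, AW112010 and Cd63, with a median of 3966 UMI, held 25 of 505 EpoR-intact and 86 of 455 EpoR-deleted mature cells untreated, and 79 of 769 and 87 of 302 after TLI-ATS. An LN cluster led by BC051142 and Cdh2 held 27.7% of EpoR-intact and 12.5% of EpoR-deleted retained cells. With each cluster given the same weight in both genotypes, the log2 ratio of Irf8 went from -0.91 to -0.84 in untreated spleen, from -0.63 to -0.49 after TLI-ATS and from -0.26 to -0.39 in LN, and that of Il12b from -0.72 to -0.61, from -0.84 to -0.64 and from -0.14 to -0.47. The count of 37 became 151 without the LN pair.

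**Figure D4:**
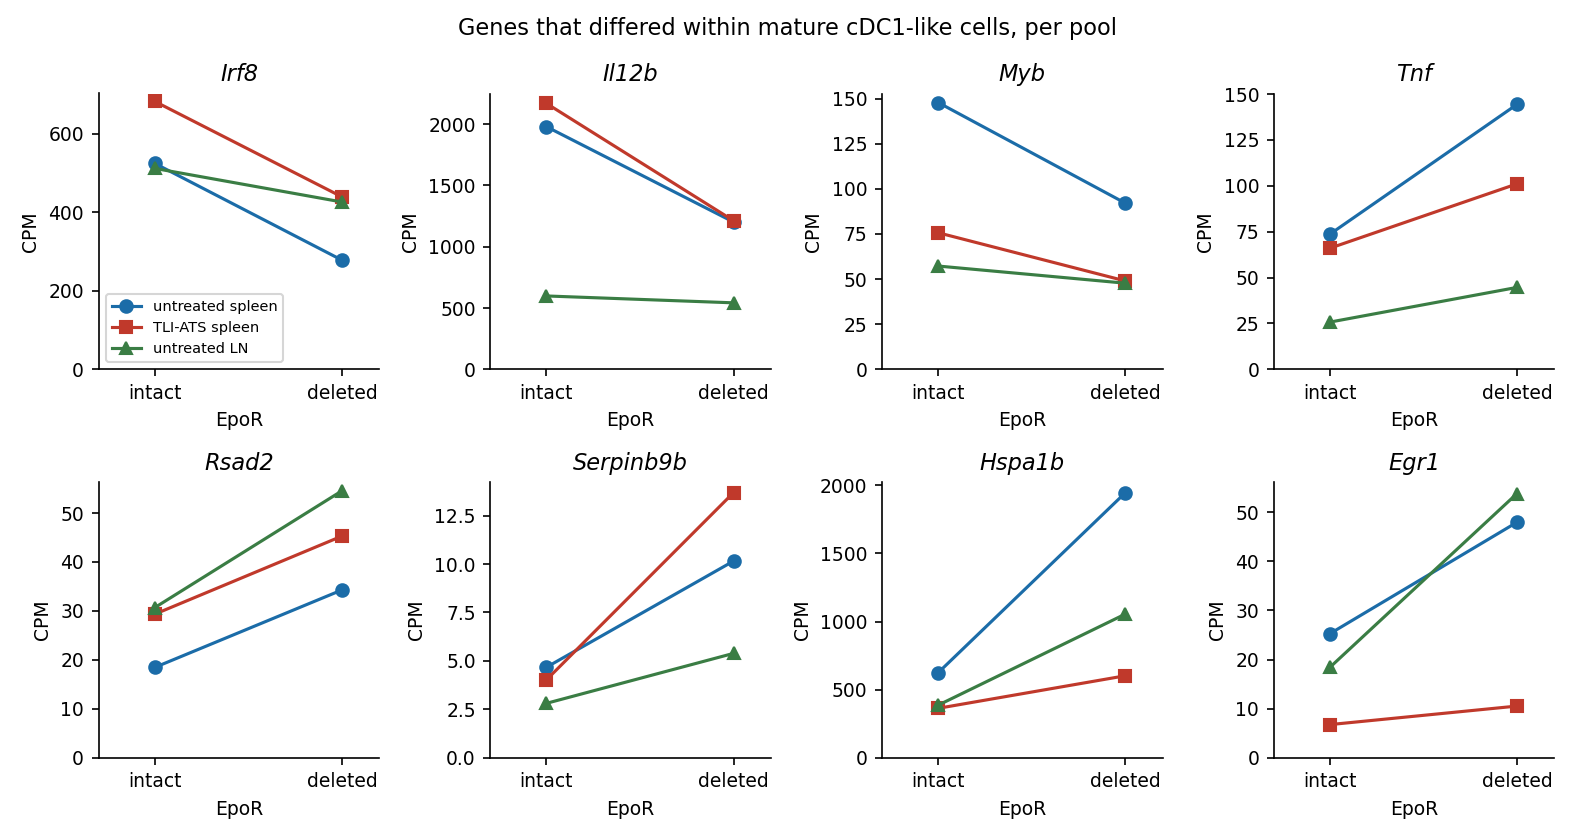
CPM (linear axis from 0, a panel per gene) of named genes within mature cells of the 6 pools of experiments 1 and 3, with lines joining the genotypes of a context. Irf8 and Il12b lie lower, and Hspa1b and Tnf higher, in the EpoR-deleted pool of each of the 3 contexts.

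Among cells outside the mature clusters, with the unnamed clusters left out as well, 26 of 13186 genes changed in edgeR (1 higher, 25 lower; 2615 at unadjusted p under 0.05). DESeq2 called 204 (50 higher, 154 lower), 21 of them shared. Xcr1 (ENSMUSG00000060509, mm10 chromosome 9, 123852315 to 123862029), the chemokine receptor that defines cDC1s and whose locus drives the Cre, fell by a log2 fold change of -0.75 (SE 0.0860, adjusted p 0.0445), with 273 against 509 CPM in untreated spleen, 384 against 635 CPM after TLI-ATS and 263 against 390 CPM in LN. Egr3 changed by -1.70 (adjusted p 0.0464) and Itgae by -1.03 (adjusted p 0.0355). Homer2 (-1.02), Dkk3 (-1.08), Slc12a2 (-1.05), the haemoglobin gene Hbb-bs (-1.12) and the genes Hsd17b13 (-2.75), Cpne4 (adjusted p 0.0355), Mybpc3 (-1.72) and Synpo (-1.59), at a few CPM or less, fell as well. Of 14 immature cDC1 genes 2 fell over all genes, and 8 were lower and 1 higher adjusted over the list alone. All 20 mature dendritic cell genes were lower here too (median -0.43), 0 over all genes and 4 adjusted over the list alone. Part of the cells counted here lay between the stages: a spleen cluster led by Il12b, Gclc and Mab21l3, with all 20 mature genes detected and 26.7% called doublets before these were removed, held 3.95% of EpoR-intact and 1.53% of EpoR-deleted untreated cells, and 2.57% and 1.02% after TLI-ATS. In LN a cluster led by Cxcl9, Naaa and Plbd1, also with all 20 mature genes detected, supplied 184 of the 205 EpoR-intact and 523 of the 559 EpoR-deleted cells of this class. Of 20 immediate early and dissociation genes 2 fell over all genes, and 5 were higher and 9 lower adjusted over the list alone. The difference from mature cells was not tested. Of 15 cDC1 identity genes 2 fell over all genes, and 6 were lower and 1 higher adjusted over the list alone. Mitochondrial transcripts had 6 of 13 lower, regulatory genes 7 of 23 lower and 1 higher, and erythroid genes 4 of 5 lower adjusted over the list alone, with 0, 0 and 1 over all genes. Unfolded protein response genes had 9 of 15 members higher and MHC class II genes 5 of 12 lower, adjusted over the list alone, with 0 over all genes. With equal cluster weights the log2 ratio of Egr3 in untreated spleen went from -2.01 to -0.65 and that of Itgae from -0.96 to -0.47, while Xcr1 went from -0.89 to -0.74. After TLI-ATS the 3 went from -1.83 to -1.07, from -1.06 to -0.62 and from -0.72 to -0.56, and in LN from -0.95 to -1.01, from -0.36 to -0.38 and from -0.57 to -0.61. The count of 26 became 2058 without the LN pair and 223 without the TLI-ATS pair, and without the untreated spleen pair 26 genes passed, 8 of them shared. With no filter beyond 1 count 937 genes passed (248 higher, 689 lower). Fitted with the genotypes of the LN pair exchanged, 181 genes passed, more than the real 26. In the simulation with gene-wise dispersions 52 of 241 calls of this test were false.

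The reporter sort asks how cDC1s that express EpoR differ from those that do not. The median of all genes lay 0.125 (log2) higher in the EpoR-positive spleen pool and 0.187 higher in the EpoR-positive LN pool, so lists are given relative to it. In TLI-ATS spleen, Hmox1 (ENSMUSG00000005413, mm10 chromosome 8, 75093618 to 75100593), the haem-degrading enzyme induced in cells that ingest red cells, stood at 184 CPM (182 to 186) in EpoR-positive and 17.6 CPM in EpoR-negative cells, a log2 ratio of 3.32. The lectin gene Cd207, a marker of a cDC1 subset that takes up dead cells, was at 119 against 43.1 CPM (1.45, interval 1.44 to 1.51), and the lipid carrier gene Apoe had a log2 ratio of 1.32. Nr4a3, a nuclear receptor gene of dendritic cell activation, was at 198 against 81.5 CPM. The pools lay in different clusters: a cluster led by Hmox1, Cd207 and Lilr4b held 2.54% of EpoR-positive and 0.0879% of EpoR-negative cells, a cluster led by Cacna1e and Slc9a9 21.5% and 3.10%, and a cluster led by Creld2 and Ccr2 1.94% and 18.4%. With equal cluster weights the log2 ratio of Hmox1 went from 3.32 to 1.59, that of Cd207 from 1.45 to 1.14, that of Apoe from 1.32 to 0.98 and that of Nr4a3 from 1.27 to 0.27. Efferocytosis and phagocytic receptor genes lay 0.46 above the median of all genes (percentile 99.2), with Elmo1 at 0.93 and the scavenger receptor gene Cd36 at 0.71. NF-kB genes lay 0.51 above it (percentile 99.8), co-stimulatory genes 0.50 (percentile 96.8), with Cd80 at 1.07 and Cd86 at 0.74, and LXR targets 0.43 (percentile 89.4). Oxidative phosphorylation genes lay 0.53 below (20 of 23 members lower), with Ndufb8 at -0.71. The random lists were matched on expression and not on genomic span, the length of the gene on the chromosome. In this contrast the longest of 5 equal groups of genes by span had a median log2 ratio of 0.6. Before subtraction the efferocytosis and NF-kB medians were 0.581 and 0.632, so a part played by span in these lists and named genes is not separated. The other named genes were Zdhhc14 (1.45), Ubc (1.32), Cmss1 (1.27), Neat1 (1.23), Zc3h12c (1.19), Aff3 (1.19) and Cacna1e (1.16) on the higher side. On the lower side were Lsm7 (-1.02), Ost4 (-0.99), Lmo1 (-0.92), H1f0 (-0.90), Creld2 (-0.88), Mrps28 (-0.88), Srm (-0.84), Gpx1 (-0.82), Rpa3 (-0.81), S100a10 (-0.81), Trmt112 (-0.79) and Fdps (-0.79). Igkc stood at 41.6 against 11.8 CPM and Hbb-bs had a log2 ratio of 1.05.

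In LN the EpoR-positive pool carried more transcripts of immature cDC1s. That list lay 0.70 and the cDC1 identity list 0.54 above the median of all genes, with Wdfy4, which cross-presentation needs, at 74.0 against 29.7 CPM (1.29, interval 1.09 to 1.55) and the dead-cell receptor gene Clec9a at 44.2 against 20.7 CPM (1.06). These LN pools were small and their tags mixed; with tags assigned by mixtures, which kept 1708 and 1924 cells, the medians of the 2 lists before that subtraction went from 0.89 and 0.72 to 0.39 and 0.39. By transcript the spleen pools of this sort were male and the LN pools female. Xist was at 281 and 197 CPM in EpoR-positive and EpoR-negative LN. Y-linked Ddx3y stood at 57.1 and 39.1 CPM in the spleen pools and at 3.71 and 1.34 CPM in the LN pools, which may thus hold spleen transcripts. In EpoR-positive spleen Clec9a was at 568 CPM. Such transcripts could make up part of the LN difference in immature cDC1 genes, which was not tested. Efferocytosis genes lay 0.39 above the median of all genes and oxidative phosphorylation genes 0.51 below it. Genomic span is not separated here either: the longest of 5 equal groups of genes had a median log2 ratio of 0.496. Slc9a9 (1.35), Cmss1 (1.18), Mctp1 (1.15), Kif26b (1.12), Arhgap15 (1.07), Plek (1.07), Rgs2 (1.06) and Nr4a3 (1.05) stood higher, and Calm4 (-0.95), Socs1 (-0.85), Ost4 (-0.82), Asprv1 (-0.80) and Spcs1 (-0.74) lower. Igkc stood at 72.1 against 14.7 CPM and the myeloid lysozyme gene Lyz2 at 1.43.

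Tested over spleen and LN with edgeR, the organ as block, 5666 of 14851 genes differed between EpoR-positive and EpoR-negative pools (2531 higher, 3135 lower; 6768 at unadjusted p under 0.05). DESeq2 called 2460, of which 2457 were shared. Hmox1 rose by a log2 fold change of 3.00 (SE 0.148, adjusted p 4.30e-22). Among the largest changes were the immunoglobulin genes Igha (3.63; at most 5.64 CPM in a pool) and Iglc1 (2.95; at most 10.0 CPM). Igkv3-1, Ighg3 and Aqp1, a water channel of red cells, also rose, at no more than 0.484, 0.806 and 0.484 CPM in any pool, so the size of their changes rests on few counts. Of 24 oxidative phosphorylation genes 20 fell and 1 rose (20 and 2 adjusted over the list alone). Of 22 efferocytosis genes 9 rose and 1 fell, and of 18 NF-kB genes 9 rose and 4 fell. The fit did not take genomic span into account. Macrophage markers, a list that includes Hmox1, rose in 8 of 11 members (9 adjusted over the list alone). Erythroid genes rose in 7 of 9 (8 adjusted over the list alone). Neutrophil genes rose in 4 of 5 members (median 1.10) and plasmacytoid dendritic cell genes in 4 of 9, with 1 lower, the same adjusted over the list alone, so transcripts of other cells rose along with the efferocytosis and NF-kB genes. Of 20 mature dendritic cell genes 10 fell and 1 rose. That list did not fall in each organ: its median over members of at least 30 CPM lay 0.11 above the median of all genes in spleen and 0.14 below it in LN, and with TMM factors it stood at -0.005 and -0.198. With spleen cells matched on UMI its median over 7 members went from 0.235 to 0.591, and that of all genes from 0.126 to 0.095. Of 16 STAT5 targets 4 rose and 4 fell (4 and 5 adjusted over the list alone). Each sort gate was a single library in both organs, so EpoR status and library cannot be told apart, and the fit with no block called 0 genes. The p-values of this edgeR test rest on the agreement of spleen and LN within the same libraries. As the LN pools may hold spleen transcripts, that agreement, for Hmox1 and other spleen genes too, does not replicate the sort.

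**Figure D5:**
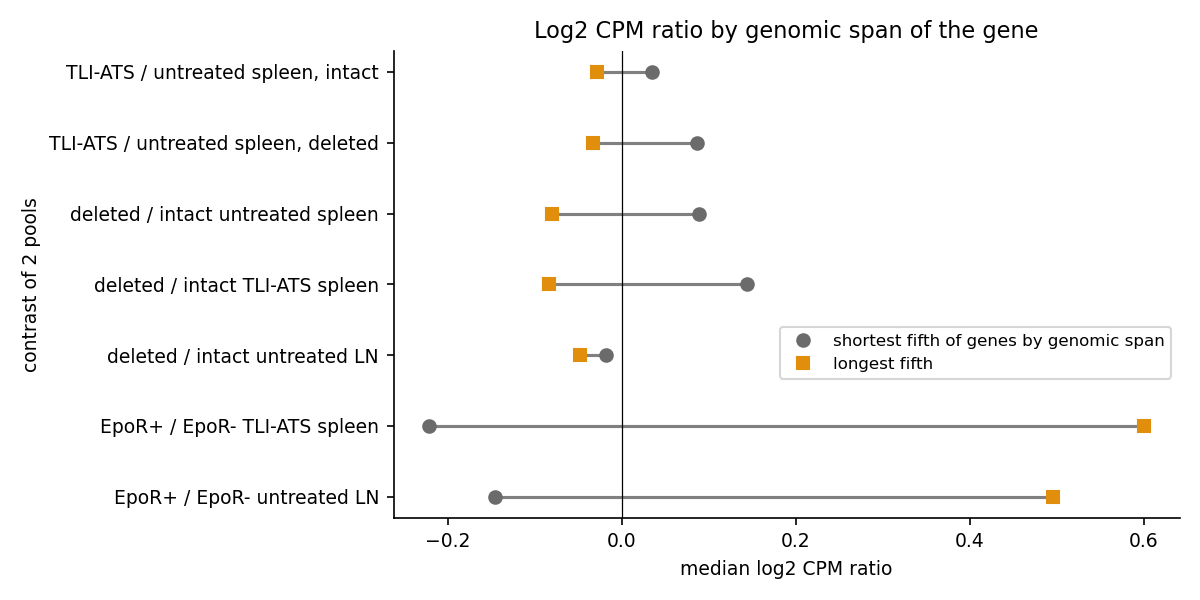
Median log2 CPM ratio (horizontal axis) of the shortest (circles) and longest (squares) of 5 equal groups of genes by genomic span, a row per single contrast. The EpoR-positive against EpoR-negative rows run from -0.22 to 0.60 in spleen and from -0.15 to 0.50 in LN. The others, from matrices of another Cell Ranger version, differ between ends by at most 0.23.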

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

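The tests of heat-shock and immediate early genes and of mature shares by tag purity, depth and sort were chosen after the results were seen; those of gene span, matched UMI and the correlation of organs were set down before. TLI-ATS went with a change in the mature share of 4.70 points in EpoR-intact and of -1.22 points in EpoR-deleted spleen, in opposite directions. The mature dendritic cell list likewise had medians of 0.359 and -0.400. Between genotypes, untreated spleen and LN lay in opposite directions for the cDC1 identity list (-0.210 and 0.207), the immature cDC1 list (-0.307 and 0.597) and the immediate early and dissociation list (-0.103 and 0.736). These differences between groups were not tested, as each rests on 1 pool per group.

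Clusters left out of the comparisons differed between the spleen pools of the sort, which drew attention as signal in cells no comparison used. A cluster led by C1qa and Vcam1, macrophage genes, held 2.64% of EpoR-positive and 0.190% of EpoR-negative spleen cells, although the stated sort gate excludes F4/80-positive cells. A cluster led by haemoglobin genes held 2.40% and 0.745%, and a cluster led by S100a8, Elane and Car1 1.87% and 0.190%. These shares were not tested.

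Heat-shock genes were higher in the EpoR-deleted pools of untreated spleen (median log2 ratio of 4 genes 1.84, 4 of 4 higher) and LN (1.21, 4 of 4 higher). A general response to tissue dissociation would raise immediate early genes as well; in untreated spleen their median was -0.409 (-0.432 to -0.384), but 5 of 15 members were higher, which does not decide, and in LN it was 0.529 (0.509 to 0.571, 11 of 12 higher), so it stays open in both. An effect of the deletion in every context would need the same direction after TLI-ATS, where the 4 genes had a median of 0.236 (0.222 to 0.249, 3 of 4 higher), which is present but small. The rule that the interval and at least 3 in 4 members must agree was set after these values were seen and replaced one on the interval alone, under which untreated spleen counted against dissociation; a sign test of the members would leave the 4 genes after TLI-ATS undecided as well. A difference in warming or handling time of the cells before pooling, the Cre itself and variation between animals were not tested and stay open, as does the genotype.

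In the EpoR-positive pools genes of long genomic span were higher and oxidative phosphorylation genes lower. Reads from introns or unspliced transcripts, which grow with span, may underlie part of it. The median log2 ratio of the longest of 5 equal groups of genes exceeded that of the shortest by 0.822 in spleen and 0.642 in LN. In the other contrasts the difference was -0.227 to -0.030. Their matrices came from Cell Ranger 6.0.0 and those of the sort from 7.0.0, so they are no reference for it. Deeper sequencing per cell is argued against for the oxidative phosphorylation genes, since with spleen cells matched on UMI (5861 per pool, medians 17402 and 17351) they stood at -0.461, against -0.403 before; the long genes were not tested in matched cells. Matching did move the mature dendritic cell list, whose median over the same 7 members went from 0.235 to 0.591. EpoR status itself and the library cannot be told apart, as each gate was 1 library. The ratios of spleen and LN correlated across 2976 genes (r = 0.904), which both predict, and genes are not independent replicates. Spleen transcripts in the LN pools could raise this correlation as well, which was not tested. Hmox1 kept 3.26 after matching, against 3.32.

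After TLI-ATS the mature share was lower in the EpoR-deleted pool. A sort on XCR1 that loses mature cells with lower Xcr1 would act in untreated spleen too, where Xcr1 was also lower; there the ratio of shares was 0.957 (0.846 to 1.083), against 0.393 (0.346 to 0.448) after TLI-ATS. Over the alternatives the untreated ratio ran from 0.779 (0.700 to 0.868, Leiden resolution 0.5) to 1.314 (1.109 to 1.556, 95% of a single tag) and the TLI-ATS ratio from 0.349 to 0.405, so such a sort is argued against as the whole cause and stays open for a part. Wrong tags are argued against by a difference of -5.652 points (-6.48 to -4.83) among cells with 95% of a single tag, and depth by -6.118 points (-6.94 to -5.31) with every cell thinned to 2000 UMI. EpoR deletion, variation between animals and their recovery from conditioning stay open and untested, since each group was 1 pool.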

How the results depend on the processing

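Mixture-based tags, all clusters kept for the tested results, clustering without the mature and immature lists, and unnamed clusters counted were alternatives added after the data were seen, and the tests by splits of pools were also chosen after; the rest were set before. Where a value moved the cause was not tested. Of the alternatives for single gene lists 973 values stayed within the counting interval, 311 moved beyond it and 3 were labelled reversed. A change of sign was labelled so only for lists at an extreme percentile in the main setting, so others may have changed sign. The 3 were the inflammatory list after TLI-ATS in EpoR-intact cells (0.016) and the STAT5 list of untreated spleen genotypes (-0.118), both at a minimum of 10 CPM, and the G2/M list after TLI-ATS in EpoR-intact cells at a 95% tag share (-0.016). Of single genes in 2 pools 789 values stayed within the counting interval and 386 moved with the same sign. Of tested genes 304 kept their side of the threshold and 128 lost it, 51 of them without the block.

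The median of the mature dendritic cell list moved as follows. With TMM factors it was 0.333 after TLI-ATS in EpoR-intact cells, and between genotypes -0.334 in untreated spleen, -1.267 after TLI-ATS and 0.029 in LN; for the sort it was -0.005 in spleen and -0.198 in LN, where TMM factors shift all ratios by 0.241. At a minimum of 10 CPM it was 0.428 and -0.460 after TLI-ATS in EpoR-intact and EpoR-deleted cells, and -0.333 and -1.290 between the untreated and TLI-ATS genotypes. At a 95% tag share these 4 were 0.533, -0.507, -0.174 and -1.265, and the sort in spleen 0.331. A pseudocount of 5 CPM gave -1.126 for the TLI-ATS genotypes and 0.215 for the sort in spleen, and doublets kept -1.286 and 0.199.

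The genotype difference in mature share was -1.73 points in untreated spleen and -7.362 after TLI-ATS at Leiden resolution 0.5. At a 95% tag share it was 1.059 in untreated spleen and -2.53 in LN, and the sort in spleen 0.859.

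The count over all cells was 39 by DESeq2 and 1 with no filter beyond 1 count, and leave-one-out gave 0 to 990 (2 without the TLI-ATS pair, 990 without the LN pair). Within mature cells it was 18 by DESeq2, 83 with no filter, 20 at a 95% tag share and 0 with no block, and leave-one-out gave 151 without the LN pair (31 of them shared with the 37), 38 without the TLI-ATS pair (29 shared; 38 higher and 0 lower) and 31 without the untreated spleen pair (23 shared). The 3 lower calls, Irf8, Il12b and Myb, were lost in the last 2, with the same sign. At a 95% tag share only Irf8 was kept, and DESeq2 lost Myb. With doublets kept 33 genes passed, all shared with the 37, and 2 of the 3 lower calls stayed. Outside the mature clusters it was 204, 937, 156 and 0 in the same order, and leave-one-out gave 26 to 2058 (223 without the TLI-ATS pair, 2058 without the LN pair; 26 without the untreated spleen pair, of which only 8 are shared with the main 26). For the sort it was 2460 by DESeq2 and 0 with no block. A 95% tag share left no cells of the EpoR-positive LN pool, so the contrasts with that pool have no value there. With 1 pool per group depth sets the counting intervals, while variation between animals is not measured.

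Each of the 10 splits of the 6 pools into 3 and 3 was fitted with the context as block, too few for a share under 0.05. In 6 of them whole contexts fall on 1 side, so the fit rests on the pair of 1 context and is no reference for the real split; they gave at most 31, 0 and 4 genes over all cells, within mature cells and outside them, the 31 being the difference of the TLI-ATS pair. Of all 10 splits 10, 1 and 2 reached the real 0, 37 and 26. Among the 4 that part every context, the highest other gave 0, 1 and 181, the last in the split that exchanges the genotypes of the LN pair only. That points to a structure of the samples; its cause was not tested, and genotype differences of opposite direction in spleen and LN or a tag key that does not hold in LN would give the same. Over all cells and within mature cells that split gave 0 and 1.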

Other observations

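Several gene groups not described above moved between the untreated and TLI-ATS spleen pools. Glycolysis and hypoxia genes stood higher after TLI-ATS in 9 of 11 members in EpoR-intact cells (median log2 ratio 0.25) and in 11 of 11 in EpoR-deleted cells (0.27), with the phosphofructokinase gene Pfkp at 0.65 and 0.57. Oxidative phosphorylation genes stood higher in 22 of 24 and 23 of 24 members (0.17 and 0.25). Migration and chemotaxis genes had medians of 0.02 and -0.25, with the chemokine receptor gene Cxcr4 at -0.96 and -1.80. Lysosomal genes had medians of -0.04 and -0.16, with the protease gene Ctsc at -0.39 and -0.87. The neutrophil genes S100a8 and S100a9 stood at 26.8 and 22.0 CPM in the EpoR-intact TLI-ATS pool, against 0.170 and 0.145 CPM untreated.

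Between genotypes, MHC class I presentation genes stood lower in the EpoR-deleted pool after TLI-ATS in 12 of 17 members (median -0.21), with H2-K1 at 1048 against 1477 CPM, and LXR targets in 5 of 6 (median -0.43), with Apol7c at 54.7 against 150 CPM and Apoe at 12.4 against 33.7 CPM. Mitochondrial transcripts stood lower in 13 of 13 members in untreated spleen (-0.17) and after TLI-ATS (-0.13). In the EpoR-positive pools, MHC class I genes lay 0.33 above the median of all genes in spleen and 0.12 in LN, mitochondrial transcripts 0.33 and 0.27, and the interferon list 0.38 and 0.34 below it. Plasmacytoid dendritic cell genes lay 0.33 above it in LN and cDC2 genes 0.44 below. The remaining lists of other cell types had under 3 members at 30 CPM in the single contrasts and have no median there.

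Of the tests that follow, that of Xcr1 was chosen after the result was seen and that of linked genes before. The Xcr1-Cre allele may lower the Xcr1 transcript itself. Outside the mature clusters the log2 fold change of Xcr1 lay -0.497 (-0.669 to -0.326) from the median of the other 13 immature cDC1 genes (-0.25), 1 of which lay lower. That interval covers the error of Xcr1 and not the spread of the other genes. Since Xcr1 was also picked after its fall was seen, this cannot decide for the allele, and a lower Xcr1 transcript by another route stays open. Zfp872 rose in the EpoR-deleted mature cells (log2 fold change 0.83, SE 0.130, adjusted p 0.00189) and lies 0.22 Mb from Epor on chromosome 9, so DNA linked to the targeted loci could differ between the genotypes. The 89 genes within 5 Mb of Epor or Xcr1 had a median absolute log2 fold change of 0.096, at percentile 37.43 of random lists, which argues against a general effect of linked DNA and leaves Zfp872 alone open. The gene model Gm10073 (ENSMUSG00000060019, mm10 chromosome 8, 106572965 to 106573432) rose by 1.22 in mature cells (adjusted p 3.07e-08) and by 1.13 outside them (adjusted p 0.00268), the change with the smallest p in mature cells; it was named after its values were seen.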
